A study of Ischnura elegans with 24 samples.

How the data were processed

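Whole bodies of male final-instar larvae of the blue-tailed damselfly Ischnura elegans were sequenced as pools of RNA. Per the labels' protocols, larvae from 3 northern and 3 southern populations were reared individually at 20 or 24 °C and fed brine shrimp nauplii. The RNA of 3 larvae was combined in each pool, with 2 pools (a and b) for every population and temperature, which gave 24 libraries from 72 larvae. The 4 latitude-by-temperature groups had 6 libraries each. Libraries were made with TruSeq chemistry and sequenced as paired ends on an Illumina HiSeq instrument, per the labels.

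The authors deposited 1 table of raw read counts for 34095 Trinity contigs, which are transcript sequences assembled from reads without a genome. Per the submitters' processing notes, FastQC 0.11.5, Trimmomatic 0.36, featureCounts and Subread 1.5.1 were used, without their roles being stated. The aligner settings, the assembly, its filters and the use of strand are not given in the sources used here. In the deposited table every contig was above 1 CPM in at least 2 libraries, so contigs had passed a filter on abundance before deposit. The contig identifiers were compared with the RefSeq gene table of the species (assembly ioIscEleg1.1), and 0 of them matched. The files do not pair contigs with gene names. The lists of named pathways chosen in advance were therefore not run, and at most 2 contigs that rose and 2 that fell are named per comparison. The contigs came from 29751 Trinity genes, and reads shared by isoforms or near-identical copies could have been split among contigs.

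Library totals were 12061616 to 17157615 counts (mean 14500287, SD 1387986). A count of 3, taken as the floor, corresponded to 0.1748 to 0.2487 CPM. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the filterByExpr filter over the 4 groups (minimum count 10, minimum total 15), which left 31287 contigs. Levels are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. Shares of counts are percentages of raw library totals. Temperature effects were fitted on all 24 libraries with 1 intercept for each of the 6 populations and a temperature effect in each latitude, by robust quasi-likelihood F tests. The difference between the 2 temperature effects tested whether the latitudes responded differently, and an F test over populations compared the 3 populations of a latitude. Because latitude varied between populations, both pools of a population were summed before latitude was tested, with 3 populations against 3. Calls are contigs with a Benjamini-Hochberg adjusted p under 0.05. SE values of log2 fold changes are those implied by the F statistics. The pools of a population came from different larvae, but larvae of a population share a source, so p-values for temperature measure the spread between pools and populations of this experiment.

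Pairing of libraries by population comes from the labels. After group means were removed, libraries of the same population at the other temperature correlated at 0.023 (northern population 2) to 0.321, while correlations with other populations lay between -0.17 and -0.016. Removing means over 3 populations pulls the latter below 0 when the former lie above it, so they add no separate evidence of pairing. Pools of 1 population and temperature differed by 13.23 to 66.23 chi-square units per degree of freedom, and no pair of libraries was identical.

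The temperature responses of the latitudes were compared across contigs by Pearson and Spearman correlation. Contigs are not independent replicates, and no p is given across them. For the relation of latitude differences to the northern response, the response came from pool a and the latitude difference from northern pool b and all southern libraries, so that no library stood on both sides. Values from 20 simulations with no effect, drawn from the fitted means and dispersions, show what shared and different libraries give by chance. The plan to choose contigs by calls on 1 pool failed, because pool a alone called 0 contigs and pool b 2. The 500 contigs with the smallest p in 1 pool were used in their place.

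Contigs are named by a rule fixed before the data were examined: an adjusted p under 0.05, a mean log2 CPM of at least 1, the same sign in each of the 3 populations (temperature) or no overlap between the population values of the latitudes, then the 2 smallest p in each direction. The tests were run first on simulated counts for 31287 contigs with 200 changed contigs each. For temperature in northern larvae 51% of 2-fold and 88% of 4-fold changes were recovered, and for southern larvae 57% and 92%. For the difference between responses the shares were 34% and 73%, for latitude at 20 °C 43% and 84%, and at 24 °C 42% and 94%. The simulated counts held no differences between populations, and changed contigs were drawn only above a minimum mean count. Latitude was tested against the spread between populations, so these shares can overstate recovery in the real latitude tests.

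Alternatives fixed before the data were examined were RLE size factors, no filter, DESeq2 1.42.0, each population or library left out, fits without population or with the pool letter, pools summed or taken as independent, limma 3.58.1 with population as a random block, and other choices of contigs and pools. Added after the data were seen were sums per Trinity gene, a fit without contigs at 0 in 10 or more libraries, a fit without libraries northern_24 2a and northern_20 1b, a new adjustment of the southern p-values without contigs at 0 in 10 or more libraries, 3 further versions of the relation to latitude and a choice of contigs on southern pools. Libraries are named by latitude, temperature, population number and pool letter. Sets of contigs that came and went together were found by average-linkage clustering of 1 minus the correlation of log2(count + 1), cut at 0.5, among contigs at 0 in at least 10 libraries, keeping sets of at least 50.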

Results

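The data were read counts of whole male larvae of Ischnura elegans, a damselfly, from 3 northern and 3 southern populations reared at 20 or 24 °C. Each of the 4 groups held 6 libraries, 2 pools of 3 larvae from each of 3 populations. The mean library total was 14630074 ± 1138969 counts (SD, n = 6) in northern larvae at 20 °C, 14811729 ± 1580964 at 24 °C, 14199628 ± 1502809 in southern larvae at 20 °C and 14359716 ± 1593108 at 24 °C. The series title sets 2 modes of evolution of plasticity under mild warming against each other, genetic compensation and genetic assimilation. The comparisons therefore ask how each latitude responded to temperature, whether the responses differed, and how latitude differences lay relative to the northern response. The files do not pair the contigs with gene names, so contigs are given by identifier.

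Latitude was the main axis of variation among libraries. The first principal component held 15.3% of the variance and separated northern from southern libraries without overlap. The second held 9.7%, with northern_24 2a farthest out at -104.57. The 20 and 24 °C libraries overlapped on each of the first 4 components.

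**Figure D1:**
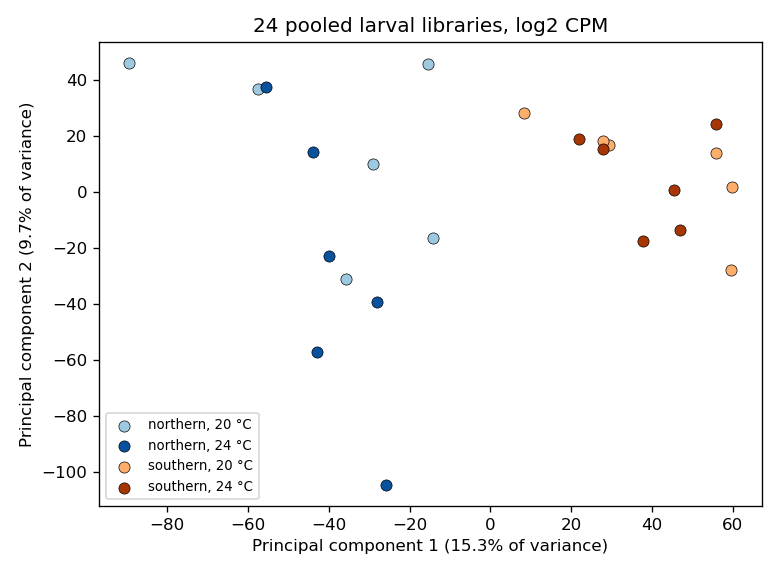
Principal components 1 and 2 of log2 CPM over tested contigs, 1 point per pooled library, coloured by latitude and rearing temperature. Northern libraries lie at negative and southern libraries at positive values of component 1, and library northern_24 2a lies lowest on component 2 at -104.57.

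Warming changed 175 contigs in northern larvae, of which 108 rose and 67 fell. Most changes were modest, with a median log2 fold change of 0.66 among those that rose and -0.63 among those that fell, and 42 contigs changed at least 2-fold. The called contigs were abundant, with a median of 4.77 log2 CPM against 1.39 for the tested contigs. Together the 108 contigs that rose took 1.64% ± 0.134 (SD, n = 6) of counts at 20 °C and 2.33% ± 0.198 at 24 °C in northern larvae, and 1.87% ± 0.102 and 1.90% ± 0.126 in southern larvae. The 67 that fell went from 0.399% ± 0.0389 to 0.244% ± 0.0315 in northern larvae and from 0.396% ± 0.0157 to 0.322% ± 0.0287 in southern larvae. These shares describe contigs chosen on the northern libraries. They are of raw library totals, without TMM scaling, and so are not on the scale of the fold changes. Mean TMM factors were 1.025 and 0.8883 in northern larvae at 20 and 24 °C, and 1.083 and 1.021 in southern larvae.

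TRINITY_DN76281_c0_g1_i1 rose from 11.19 ± 2.059 CPM (SD, n = 6) to 35.34 ± 5.395 CPM in northern larvae, a log2 fold change of 1.67 ± 0.16 (SE, edgeR adjusted p = 5.24e-05). It also rose in southern larvae, from 15.27 ± 6.96 to 26.75 ± 7.53 CPM (0.82 ± 0.16, edgeR adjusted p = 0.0477), a call that ended when contigs at 0 in 10 or more libraries were left out of the adjustment or of the fit (adjusted p 0.149 and 0.147, log2 fold change 0.817 in that fit). TRINITY_DN69847_c1_g2_i1 rose from 23.61 ± 4.967 to 66.17 ± 15.42 CPM in northern larvae (1.48 ± 0.15, edgeR adjusted p = 0.000105). TRINITY_DN173612_c0_g1_i2 fell from 212.4 ± 8.76 to 145.1 ± 15.53 CPM (-0.55 ± 0.06, edgeR adjusted p = 0.000269), and its highest library at 24 °C (168.6 CPM) lay below its lowest at 20 °C (203.5 CPM). TRINITY_DN224631_c0_g4_i1 fell from 45.49 ± 11.87 to 15.68 ± 6.119 CPM (-1.59 ± 0.19, edgeR adjusted p = 0.000348). Each of the 175 contigs moved the same way in all 3 northern populations, as did 31.89% of the tested contigs. The count ranged from 28 to 326 with 1 population or library left out. It was 79, 28 and 39 without northern populations 1, 2 and 3, and 108 and 98 without southern populations 1 and 2. It rose to 326 without northern_20 1a, and it fell to 70 without northern_24 1a, 100 and 69 without northern_20 2a and 2b, 115 without northern_24 2b, 97 and 84 without northern_20 3a and 3b, and 86 and 107 without northern_24 3a and 3b. It was 2 when both pools of a population were summed. With pools summed the contigs named here as falling no longer passed (edgeR adjusted p = 0.252 and 0.197), with log2 fold changes of -0.56 and -1.58. DESeq2 called 852 contigs, 163 of the 175 among them.

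In southern larvae 11 contigs were called for temperature with the same direction in all 3 populations, of which 5 rose and 6 fell. TRINITY_DN121930_c0_g1_i6 rose from 9.79 ± 1.503 CPM (SD, n = 6) to 23.76 ± 4.635 CPM (1.27 ± 0.18, edgeR adjusted p = 0.00588) and rose as far in northern larvae (1.29 ± 0.18, edgeR adjusted p = 0.00186). TRINITY_DN176168_c0_g1_i1 rose from 51.0 ± 3.776 to 71.97 ± 10.54 CPM (0.49 ± 0.09, edgeR adjusted p = 0.0381). TRINITY_DN155481_c0_g1_i1 fell from 3.811 ± 0.5833 to 2.107 ± 0.2708 CPM (-0.85 ± 0.15, edgeR adjusted p = 0.0381). TRINITY_DN281742_c0_g1_i1 fell from 15.85 ± 1.518 to 10.37 ± 1.331 CPM (-0.61 ± 0.11, edgeR adjusted p = 0.0381), and also fell in northern larvae (-0.49 ± 0.11, edgeR adjusted p = 0.049). Of 38 alternatives each, these 4 contigs did not pass the threshold in 6, 20, 21 and 21 (adjusted p up to 0.711, 0.802, 0.741 and 0.741).

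The full southern count was 33 contigs, 27 that rose and 6 that fell. The other 22 belonged to a set of 127 contigs counted in the 4 libraries of northern population 1 and in both 24 °C pools of southern population 2. Their summed counts were 3346 to 6834 in those 6 libraries and at most 9 in each of the other 18. Without contigs at 0 in 10 or more libraries, a setting chosen after the data were seen, 1 call was made in southern larvae. That setting takes the 22 contigs of the set out of the test. The log2 fold changes of the other 11 moved by at most 0.00117, and 1 of them, TRINITY_DN121930_c0_g1_i6, was left when the p-values of the full fit were adjusted again without contigs at 0 in 10 or more libraries. Their adjusted p, from 0.00588 to 0.0499 in the full fit, was then 0.0311 to 0.149, so the 10 calls ended with the adjustment and not with the folds. The count was 0 without southern population 2, 2 without northern population 1, 0 in the fit without population and 0 with pools summed.

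**Figure D2:**
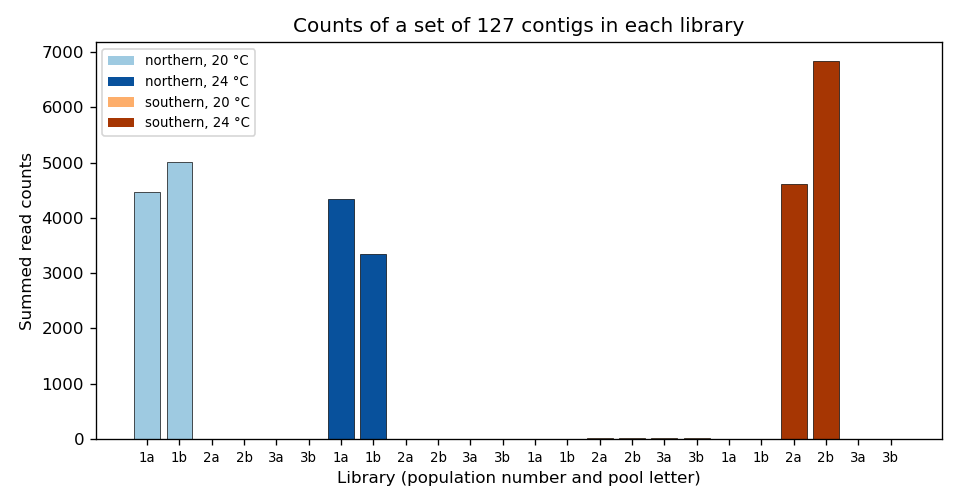
Summed read counts of the set of 127 contigs (vertical axis) in each of the 24 libraries, named by population number and pool letter and coloured by group. The bars reach 3346 to 6834 counts in the 6 libraries of northern population 1 and southern population 2 at 24 °C, and at most 9 elsewhere.

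The direction of the responses was then compared between latitudes. Over all 31287 tested contigs 60.4% had the same sign in both. Of the 175 contigs called in northern larvae, 160 (91.43%) had the same sign in southern larvae, 99 of them at an unadjusted p under 0.05, while of the 33 called in southern larvae 12 (36.36%) had the same sign in northern larvae. These were all 11 southern calls outside the set of 127 and 1 of the 22 within it. The northern and southern calls shared 6 contigs, all in the same direction, where independent lists would share 0.185. Across the tested contigs the northern and southern log2 fold changes correlated at r = 0.208 (Spearman rho 0.253), with no library in common. The mean covariance of responses was 0.051 between northern populations, 0.0125 between southern populations and 0.0294 between a northern and a southern population.

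The size of the responses was compared on contigs chosen in 1 pool of a latitude. Among the 500 contigs with the smallest p in northern pool a, the mean log2 response along the direction seen in pool a was 0.469 in northern pool b and 0.166 in southern larvae. With the pools exchanged it was 0.446 in northern pool a and 0.242 in southern larvae. Both pools of a population share its source, which favours the latitude that gave the choice. For 500 contigs chosen on southern pool a the mean was 0.165 in southern pool b and 0.193 in northern larvae, and for those chosen on southern pool b it was 0.071 in southern pool a and 0.186 in northern larvae. The northern covariance exceeded the southern by 0.0385, the highest of the 10 ways to part 6 populations into 3 and 3 (next highest 0.0347), and 10 splits cannot give an exact permutation p below 0.1. The northern covariance (0.051) was 0.0321 without northern population 2, and the southern one (0.0125) was 0.0074 without southern population 1 and 0.0192 without southern population 3.

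**Figure D3:**
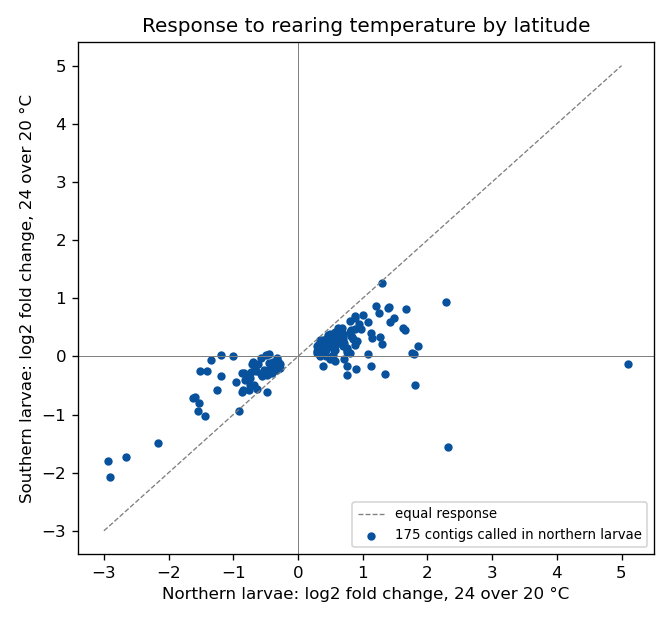
Log2 fold change from 20 to 24 °C in southern larvae (vertical axis) against northern larvae (horizontal axis) for the 175 contigs called in northern larvae, with a dashed line of equal response. Most points share their sign (160 of 175), and choosing contigs on the northern libraries draws the northern values away from 0.

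The test of the difference itself called 8 contigs whose response differed between latitudes. TRINITY_DN5756_c7_g1_i4 went from 10.2 ± 2.151 CPM (SD, n = 6) to 17.41 ± 8.549 CPM in northern larvae and from 10.7 ± 1.103 to 6.722 ± 1.255 CPM in southern larvae. The difference of its log2 responses was -1.37 ± 0.23 (SE, edgeR adjusted p = 0.0318), while neither response alone passed the threshold (edgeR adjusted p = 0.051 and 0.156). It did not pass in 24 of its 38 alternatives (adjusted p up to 0.948). The other 7 were members of the set of 127 contigs. None of the 8 was left without contigs at 0 in 10 or more libraries, without population in the model or with pools summed (0 calls in each). At an unadjusted p under 0.05 there were 1519, 1637 and 1345 contigs in these settings and 1618 in the main fit. With 31096 contigs tested in the first setting and 31287 in the others, these numbers lie near or below the share of 0.05 that chance alone gives. The first of these settings takes the 7 contigs of the set out of the test, and the difference of TRINITY_DN5756_c7_g1_i4 stayed at -1.37, -1.44 and -1.4 in the 3 settings. DESeq2 called 15 contigs.

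At 24 °C southern and northern larvae differed in 155 contigs, 60 higher and 95 lower in southern larvae, with 113 differing at least 2-fold. The 60 contigs took 0.381% ± 0.111 (SD, n = 6) of counts in southern and 0.117% ± 0.0131 in northern larvae at 24 °C. TRINITY_DN7599_c0_g4_i3 was at 20.82 ± 15.08 CPM in southern and 0.8513 ± 0.3772 CPM in northern larvae (log2 difference 4.58 ± 0.17, edgeR adjusted p = 0.000432). TRINITY_DN1332_c14_g5_i7 was at 20.2 ± 9.924 and 1.099 ± 0.4443 CPM (4.23 ± 0.24, edgeR adjusted p = 0.00303). Single southern libraries ranged from 6.097 to 42.27 CPM for TRINITY_DN7599_c0_g4_i3 and from 8.539 to 36.99 CPM for TRINITY_DN1332_c14_g5_i7, so these SE hold for population sums. TRINITY_DN5478_c18_g1_i2 was lower in southern larvae, at 3.969 ± 3.325 against 27.61 ± 22.6 CPM (-2.78 ± 0.16, edgeR adjusted p = 0.00303). Its single libraries overlapped, from 0.2076 to 8.314 CPM in southern and from 1.082 to 51.79 CPM in northern larvae, so here too the small SE holds for population sums. It no longer passed the threshold in 10 of its 27 alternatives (adjusted p up to 0.473), among them those without northern_24 1a or 2a and without southern_24 1a, 2a or 2b. TRINITY_DN2057_c5_g1_i4 was at 3.335 ± 1.392 against 22.62 ± 8.286 CPM (-2.73 ± 0.16, edgeR adjusted p = 0.00306). It did not pass in 2 alternatives, 1 of them without northern_24 3b (adjusted p up to 0.0582), and TRINITY_DN7599_c0_g4_i3 did not pass without southern_24 2b (0.0636). The count was 15 without southern population 2, 16 without southern_24 2b and 322 without northern_24 2a, and DESeq2 called 1449 contigs.

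At 20 °C edgeR called 0 contigs between latitudes, and DESeq2 called 918. At an unadjusted p under 0.05 edgeR had 4499 of the 31287 contigs at 20 °C and 4482 at 24 °C. The 0 and 155 calls therefore do not show that the latitudes differed at 24 °C only. TRINITY_DN7599_c0_g4_i3 differed by 1.75 ± 0.47 at 20 °C and TRINITY_DN1332_c14_g5_i7 by 2.89 ± 0.91 (edgeR adjusted p = 0.241 and 0.275). Library northern_20 1a held the second of these contigs at 10.7 CPM, against 0.4814 to 1.016 CPM in the other 5. Its difference at 20 °C was 4.46 without northern_20 1a and 2.28 without northern_20 1b (edgeR adjusted p = 0.133 and 0.517; 0.133 to 0.517 over the 12 libraries left out in turn). The same contigs that were higher in southern larvae at 24 °C took 0.344% ± 0.118 (SD, n = 6) of counts in southern and 0.164% ± 0.0564 in northern larvae at 20 °C. The limma fit with population as a random block called 194 contigs, and the 24 libraries taken as independent gave 457.

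Southern larvae at 24 °C and northern larvae at 20 °C differed in 150 contigs, 72 higher and 78 lower in southern larvae, and 104 of them by at least 2-fold. TRINITY_DN73177_c1_g2_i2 was at 15.5 ± 13.37 CPM in southern larvae at 24 °C and 1.045 ± 0.4041 CPM (SD, n = 6) in northern larvae at 20 °C (3.87 ± 0.18, edgeR adjusted p = 0.00107). Its single libraries overlapped, from 1.151 to 33.15 CPM in southern and up to 1.607 CPM in northern larvae, so this SE too holds for population sums, and limma gave a log2 difference of 3.08 (adjusted p 0.224, the highest of its alternatives). TRINITY_DN122976_c1_g3_i1 was at 23.69 ± 14.03 and 5.827 ± 2.457 CPM (1.98 ± 0.15, edgeR adjusted p = 0.0139). TRINITY_DN278615_c1_g1_i1, an abundant contig, was at 318.7 ± 119.5 against 768.3 ± 253.1 CPM (-1.27 ± 0.10, edgeR adjusted p = 0.0139), with single libraries up to 480.1 CPM in southern and down to 392.4 CPM in northern larvae. TRINITY_DN222727_c0_g6_i6 was at 2.493 ± 0.6853 against 9.975 ± 2.743 CPM (-1.99 ± 0.16, edgeR adjusted p = 0.0139). Of 27 alternatives each, these 4 contigs did not pass in 4, 10, 10 and 3 (adjusted p up to 0.224, 0.0911, 0.191 and 0.0928). The list shared 33 contigs with the 24 °C list, all in the same direction, where independent lists would share 0.743, and the southern 24 °C libraries entered both. The count fell to 4 without southern_24 1b and 5 without southern population 2, and rose to 507 without northern population 3.

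Populations of 1 latitude were compared by F tests, which called 217 contigs among northern and 34 among southern populations. The set of 127 contigs supplied 96 of the northern and 28 of the southern calls. Without contigs at 0 in 10 or more libraries the counts were 58 and 1, and other groupings of the libraries then reached 168 and 1. With 1 population left out the northern count was 31, 445 and 63 without northern populations 1, 2 and 3, and 118 without southern population 2. It was 334 and 142 without northern_20 1a and 1b, 114 and 110 without northern_24 1a and 1b, 331 without northern_20 2b, 104 without northern_20 3a and 136 without southern_24 2b. The southern count was 0 and 58 without northern populations 1 and 2, and 12 and 1 without southern populations 1 and 2. It was 9 without any 1 library of northern population 1, 54 without northern_24 2a, 14, 16 and 10 without southern_24 1a, 2a and 2b, 58 without southern_20 3a, and 0 with cell means.

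Latitude differences were then set against the northern temperature response, since compensation predicts opposite signs. With no library on both sides, the northern response and the southern-minus-northern difference at 24 °C correlated at r = -0.153 across contigs (rho -0.125, covariance -0.045), and at r = -0.074 (covariance -0.023) with the pools exchanged. At 20 °C the values were r = -0.01 (covariance -0.003) and 0.049 (covariance 0.013). Over all contigs the latitude difference was opposite in sign to the northern response in 55.4% at 24 °C and 50.9% at 20 °C (53.5% and 49.4% with the pools exchanged). Among the 500 contigs chosen on pool a, 72.8% had a latitude difference at 24 °C opposite to the northern response and 54.2% at 20 °C. With the choice on pool b the shares were 70.6% and 60.4%. Along the direction of the northern response these contigs lay lower in southern larvae by a mean log2 difference of -0.434 and -0.379 at 24 °C and of -0.13 and -0.175 at 20 °C. By definition the step between the temperatures in these values is the southern minus the northern response.

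Libraries shared by both sides changed this relation. With the same northern libraries on both sides the correlation was -0.378 at 24 °C and 0.277 at 20 °C, and simulations with no effect gave -0.508 and 0.495 on average. The covariance with shared libraries was -0.083 at 24 °C against -0.059 simulated, and 0.059 at 20 °C against 0.056. With different libraries the simulated covariances lay between -0.003 and 0.006 at 24 °C and between -0.005 and 0.002 at 20 °C. At 20 °C the value with the pools exchanged (0.013) lay above that range too, and the simulations hold no differences between populations. When the response came from 1 northern population and the difference from the other 2, the covariance at 24 °C was -0.032 for population 1, 0.024 for population 2 and -0.044 for population 3. At 20 °C these values were -0.003, 0.048 and -0.033, as wide a spread at a temperature where the pools gave -0.003 and 0.013. The 7 contigs called both for temperature in northern larvae and for latitude at 24 °C all had opposite signs, from lists that share the northern 24 °C libraries. Conversely, 8 contigs were called both for temperature in northern larvae and between southern larvae at 24 °C and northern larvae at 20 °C. All 8 had the same sign, from lists that share the northern 20 °C libraries, so neither overlap decides between the modes.

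**Figure D4:**
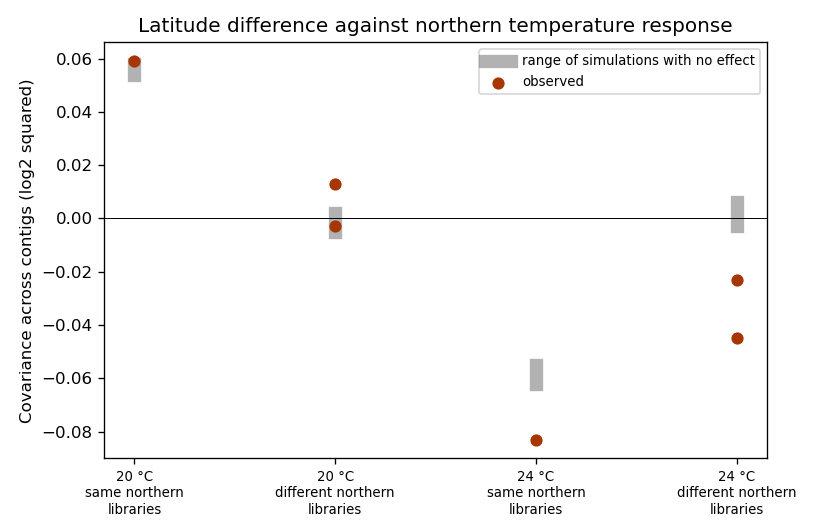
Covariance across contigs between the northern temperature response and the southern-minus-northern difference at 20 and 24 °C (points), with the range of 20 simulations without effects (grey bars), for the same or different northern libraries on both sides. At 24 °C the observed values with different libraries, -0.045 and -0.023, lie below the simulated range of -0.003 to 0.006, and at 20 °C the value 0.013 lies above -0.005 to 0.002.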

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

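The tests of the response of southern larvae in the set of 127 contigs, of shared libraries and single populations, of depth, of composition and of the size of the northern response, and regroupings and an adjustment that leave aside contigs at 0 in 10 or more libraries, were chosen only after the results were seen. Among 92 groups of 6 libraries examined with Dixon's ratio, 10 had a library set apart, and chance alone sets apart about 1 in 20 if values are normal. That rate does not hold for counts of contigs at least 8-fold above every other library. These counts are mostly 0, and a single library above 0 is then set apart. The share of counts taken by the most abundant contig was 3.948% in northern_20 1b, against 7.111% to 8.521% in the other 5 libraries of its group. Contigs at least 8-fold above every other library numbered 112 in northern_24 2a, 39 in northern_20 1b and 7 in southern_20 3b, against at most 1 in other libraries of their groups. TRINITY_DN76281_c0_g1_i1 was at 29.21 CPM in southern_20 3b, above the 10.32 to 13.95 CPM of the other 5. TRINITY_DN121930_c0_g1_i6 was at 19.57 CPM in northern_24 3a, below the others (35.2 to 45.11 CPM). TRINITY_DN281742_c0_g1_i1 was at 12.94 CPM in southern_24 2b, above the others (9.081 to 10.3 CPM). TRINITY_DN1332_c14_g5_i7 was at 10.7 CPM in northern_20 1a and 0.3533 CPM in northern_24 3a, outside 0.4814 to 1.016 and 1.035 to 1.732 CPM. TRINITY_DN122976_c1_g3_i1 was at 2.159 CPM in southern_20 2b, below the others (12.26 to 25.19 CPM). The test of the difference between the temperature responses called 8 contigs, of which 7 belonged to the set of 127.

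The first pattern is that 22 of the 33 southern temperature calls and 7 of the 8 calls for a difference between latitudes came from contigs counted in 6 libraries. A response of southern larvae to warming is argued against, since the set rose in 1 of 3 southern populations. Exchange of reads among these 6 libraries is argued against by contigs peculiar to northern_20 1b, whose median level in the other 5 was 0.909 of that in the remaining 18, and by the lack of a donor, since the set took 0.02279% to 0.04599% of counts in each of the 6 and its mean share in the 2 southern libraries was 1.41 times that in the 4 northern ones. Scaled to its own total, the set varied no more than counting error over the 6 libraries (median squared coefficient of variation beyond counting -0.00191). The value was 0.0687 for 475 contigs of like level (ratio -0.0278). Those contigs were scaled to library totals, and the set was found by correlation, so the ratio is not like for like and decides nothing. A candidate explanation is 1 outside source of RNA or reads common to the 6 libraries, such as another organism or another library handled with them. The contigs' identity was not examined.

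The second pattern is that 175 contigs were called in northern and 33 in southern larvae. The median variance between pools of southern larvae was 0.8875 of the northern one. This value cannot decide whether a larger southern spread lowered the southern count, since both latitudes were tested against 1 spread estimated from all 24 libraries. Depth is argued against by northern totals 1.031 of southern totals. Composition stays open, because RLE factors (ratio of northern to southern calls 5.83) kept 168 of the 175 northern calls and so changed too little to test it, while northern libraries at 24 °C had a mean TMM factor of 0.8883 (other groups 1.021 to 1.083) and 9.159% of counts in the most abundant contig (7.159% to 7.479%). A larger response of northern larvae may account for it: 1 of the 10 splits of populations, the real one, gave a covariance difference of 0.0385, with the next at 0.0347, and 10 splits are too few to decide. It stays a hypothesis, since the test of the difference called 1 contig outside the set of 127.

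The third pattern is the negative relation at 24 °C between the northern response and the latitude difference. Shared libraries as its whole cause are argued against by the covariances of -0.045 and, with the pools exchanged, -0.023 with different libraries, though at 20 °C such a covariance also reached 0.013. Departures of single northern populations at 24 °C, which both pools of a population share, may contribute, since 1 of the 3 northern populations gave a covariance above 0 (0.024) against the others, and at 20 °C the values of single populations spread as far (-0.033 to 0.048). By definition the latitude difference at 24 °C is that at 20 °C plus the southern minus the northern response. The third pattern is therefore not independent of the second. For the 500 contigs chosen on pool a the responses were 0.469 in northern pool b and 0.166 in southern larvae. Their latitude difference went from -0.13 at 20 °C to -0.434 at 24 °C. Compensation, the biological reading named in the title, stays open beside departures of single populations.

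Chance was examined by regrouping libraries or populations. For temperature 1 of 40 groupings within populations, the real one, called as many contigs. Other groupings called at most 4 against 175 in northern larvae and at most 13 against 33 in southern larvae. The northern count thus stood apart from regroupings of single pools within these populations, though 40 groupings give no share below 1 of 40. Differences among populations in their response were not regrouped, and with pools summed the northern count was 2. For populations of a latitude 1 of 40 groupings called as many. Other groupings called at most 162 against 217 in the north and at most 1 against 34 in the south. The set of 127 contigs, which came and went as a whole, supplied 22 of the 33 southern temperature calls. It also supplied 96 and 28 of the northern and southern population calls. Regrouping libraries cannot separate such a block from chance, so no conclusion is drawn from these 3 full counts.

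Much of 3 of these counts came from the set of 127 contigs, so the groupings were also compared without contigs at 0 in 10 or more libraries. With these contigs out of the fit and the adjustment, the real and the highest other counts were 181 and 4 for temperature in northern larvae (1 of 40 groupings called as many), 1 and 3 in southern larvae (5 of 40), 58 and 168 among northern populations (2 of 40) and 1 and 1 among southern populations (4 of 40). The northern temperature count thus stood apart from regroupings of pools within populations, and the other 3 counts did not. The 168 came from a single grouping that put together 3 of the 4 libraries of northern population 1 and 3 of the 4 of northern population 3. A count that high points to some structure among the northern libraries, and which one was not tested. Counted outside these contigs in the fit that holds them, the values were 175 and 4 (1 of 40), 11 and 3 (1 of 40), 121 and 161 (2 of 40) and 6 and 1 (1 of 40), but there the adjusted p of the southern calls drew on the small p-values of the set, since 1 of the 11 was left when p-values were adjusted without these contigs. The number of southern calls outside the set is therefore not separated from chance. These regroupings concern counts of calls and not the direction of responses. Of the 175 contigs called in northern larvae 160 had the same sign in southern larvae, against 60.4% of all tested contigs.

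The 10 splits of 6 populations are too few for a share under 0.05. The real and the highest other counts were 8 and 6 for the difference between responses, 0 and 10 for latitude at 20 °C (10 of 10 splits called as many), 155 and 0 at 24 °C, and 150 and 2 for southern larvae at 24 °C against northern larvae at 20 °C.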

How the results depend on the processing

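Settings with contigs summed per Trinity gene, contigs at 0 in 10 or more libraries left out of the fit or of the adjustment alone, libraries northern_24 2a and northern_20 1b left out, 500 contigs chosen per pool, single northern populations or the mean of both temperatures were chosen after the data were seen. The 17 named contigs kept their direction in all 558 combinations with an alternative, and 134 of these no longer passed the threshold. Counts of calls moved by over 1.5 times in many settings, and the cause was not tested unless stated. Gene lists were not run, since contigs carry no names.

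For temperature in northern larvae (175) the count was 852 with DESeq2 and 2 with pools summed. Summing leaves fewer libraries, and its error comes from how the measured responses of populations differ, which includes differences between the larvae sampled. The main fit draws its error also from the direct comparison of pools within a population and temperature. Which of these lowered the count was not tested. For southern larvae (33) it was 18 without a filter, 62 with DESeq2, 0 with pools summed, 1 without contigs at 0 in 10 or more libraries (also 1 when they were left out of the adjustment alone) and, for pairing by population, 0 with no population block. For the difference between responses (8) it was 15 with DESeq2, 0 with no population block, 0 with pools summed, 0 without contigs at 0 in 10 or more libraries and 2 without northern_24 2a and northern_20 1b. Among northern populations (217) it was 537 with DESeq2, 58 without contigs at 0 in 10 or more libraries and 116 without those 2 libraries. Among southern populations (34) these counts were 106, 1 and 11, and cell means gave 0.

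For latitude at 20 °C (0) DESeq2 called 918, the 24 libraries as independent 457, limma with population as a random block 194 and the 12 population sums in 1 fit 3. At 24 °C (155) the counts were 1449, 1423, 900 and 367, with 501 without a filter, 79 per Trinity gene and 322 without northern_24 2a and northern_20 1b. For southern larvae at 24 °C against northern larvae at 20 °C (150) they were 1741, 1173, 575 and 98, with 89 without a filter and 25 without those 2 libraries. Treating pools as independent counts 2 pools of a population as 2 replicates of a latitude.

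The pool letters do not pair libraries: letters correlated at -0.072 to 0.057 across temperatures. With the letter as a replicate block the counts were 127 for temperature in northern larvae, 10 in southern larvae, 4 for the difference and 138 and 10 among northern and southern populations. For latitude the letter can only enter with the pools unsummed, so its counts stand beside those of the 24 libraries as independent: 378 against 457 at 20 °C, 1277 against 1423 at 24 °C and 960 against 1173 for southern larvae at 24 °C against northern larvae at 20 °C.

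Leaving out 1 population or library gave 28 to 326 calls for temperature in northern larvae: 79, 28 and 39 without northern populations 1, 2 and 3, 108 and 98 without southern populations 1 and 2, 326 without northern_20 1a, 70 without northern_24 1a, 100 and 69 without northern_20 2a and 2b, 115 without northern_24 2b, 97 and 84 without northern_20 3a and 3b, and 86 and 107 without northern_24 3a and 3b. In southern larvae the range was 0 to 45: 2 without northern population 1, 0 and 17 without southern populations 2 and 3, 7 and 12 without northern_20 1a and 1b, 7 without northern_24 1a or 1b, 2 without southern_20 2a or 2b, 8 and 9 without southern_24 2a and 2b, 19 without southern_20 3a and 14 without southern_24 3b. For the difference it was 0 to 17: 0 without northern population 1, southern population 2, northern_20 1b, northern_24 1a or 1b, southern_20 2a or 2b, 2 without northern_20 1a, southern_24 2a or 2b, 14 and 15 without southern and northern population 3, 15 without northern_24 2a or 2b, 16 without southern_20 3b, and 17 without northern_24 3b or southern_24 3a.

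Among northern populations the range was 31 to 445: 31, 445 and 63 without northern populations 1, 2 and 3, 118 without southern population 2, 334 and 142 without northern_20 1a and 1b, 114 and 110 without northern_24 1a and 1b, 331 without northern_20 2b, 104 without northern_20 3a and 136 without southern_24 2b. Among southern populations it was 0 to 58: 0 and 58 without northern populations 1 and 2, 12 and 1 without southern populations 1 and 2, 9 without northern_20 1a or 1b or northern_24 1a or 1b, 54 without northern_24 2a, 14, 16 and 10 without southern_24 1a, 2a and 2b, and 58 without southern_20 3a.

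For latitude at 20 °C the range was 0 to 17: 17 without northern population 3, 1, 2 and 2 without southern populations 1, 2 and 3, and 1 without northern_20 2a. At 24 °C it was 15 to 322: 54 and 49 without northern populations 2 and 3, 33, 15 and 77 without southern populations 1, 2 and 3, 53, 322, 43, 82 and 43 without northern_24 1a, 2a, 2b, 3a and 3b, and 45, 46, 16 and 64 without southern_24 1b, 2a, 2b and 3b. For southern larvae at 24 °C against northern larvae at 20 °C it was 4 to 507: 19, 9 and 507 without northern populations 1, 2 and 3, 17, 5 and 24 without southern populations 1, 2 and 3, 32, 25, 67, 42, 23 and 409 without northern_20 1a, 1b, 2a, 2b, 3a and 3b, and 226, 4, 49, 8 and 46 without southern_24 1a, 1b, 2a, 2b and 3b.

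The correlation of southern with northern responses (0.208) was 0.15 to 0.21 with 1 population left out, 0.31 for contigs with a mean log2 CPM of at least 2, 0.039 without a filter, 0.151 with northern pool a, 0.75 for contigs called in northern larvae, 0.721 for those at least 2-fold, and 0.131 and 0.284 for 500 contigs chosen on pool a and b. The correlation of the northern response with the latitude difference at 20 °C (-0.01) was -0.052 to 0.088 with 1 population left out, 0.277 with the same libraries on both sides, 0.495 for called contigs, 0.59 for those at least 2-fold, -0.147 for 500 contigs chosen on pool b and 0.12 with the response of northern population 2 alone. At 24 °C (-0.153) these were -0.181 to -0.075, -0.378, -0.64, -0.598, -0.238 and 0.057, with -0.362 for 500 contigs chosen on pool a, -0.074 with pool b giving the response, -0.235 for a mean log2 CPM of at least 2 and -0.226 without a filter. Called contigs were chosen on both pools, so their values share libraries with the choice. For the mean of both temperatures (-0.091) the values were -0.131 to -0.021 with 1 population left out, -0.176 for called contigs, -0.256 and -0.223 for 500 contigs chosen on pool a and b, and 0.099 with northern population 2 alone.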

Other observations

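The sets of contigs and the library counts below were defined after the data were seen. Besides the set of 127, 4 sets of contigs rose and fell together across libraries, and 1 of their contigs passed the filter for testing. The first, of 409 contigs, had 42900 summed counts in northern_24 2b, 18353 in northern_24 3a and 14814 in southern_20 1b, then 1540 in northern_24 1b (over 313 of its contigs) and 1239 in southern_20 1a (over 299), and at most 780 in each other library. The second, of 260 contigs, had 16798 counts in northern_24 3a, 10015 in northern_24 1a and 9027 in northern_24 2a, then 898 in northern_20 3a and 813 in northern_24 1b, and at most 89 elsewhere. The third, of 57 contigs, had 29193 counts in northern_24 2a 5279 in southern_20 3b and 470 in southern_24 3b (over 38 of its contigs), and at most 64 elsewhere. The last, also of 57 contigs, was counted mainly in northern_20 2b (1581 counts) and the 4 libraries of northern population 1 (358 to 1196 counts), with at most 127 elsewhere. None of the tested contigs in these 4 sets was called in any comparison.

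The 112 contigs far above every other library in northern_24 2a took 2.98% of its counts, and the 39 in northern_20 1b took 0.862%. Their median number of other libraries at 0 was 0 and 1 of 23, so these contigs were also counted at low levels in most libraries. Contigs at 0 in all 12 southern libraries numbered 194, against 18 at 0 in all northern libraries. Most of the 194 came from the set of 260 contigs, of which no southern library counted more than 27. Libraries northern_24 1a, 2a and 3a counted 260, 260 and 258 of them. The 194 contigs are therefore largely 1 block held by a few northern libraries, and not separate differences between latitudes. Among the 18 other triples of populations the number at 0 ranged from 0 to 131, and the triples with 125 or more were those that leave out northern population 1 and southern population 2, the populations that hold the set of 127.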
